A study of Homo sapiens with 8 samples.

How the data were processed

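The series measured gene expression in 4 human multiple myeloma cell lines, KMS11, KMS18, KMS34 and OPM2, all of which carry the t(4;14) translocation per the labels. In each line, 1 culture received a control and 1 a knockdown of MMSET I, the short isoform of the histone methyltransferase gene NSD2 (also called MMSET), so that there were 4 control and 4 knockdown arrays, 8 in all. Per the labels' protocols, cells were infected with lentivirus in 8 µg/mL polybrene, the medium was changed after a day, and RNA was extracted after a further 48 h. The series text gives 72 h of shRNA treatment and names only KMS11. The shRNA sequences and the nature of the control were not given in the sources used here. Biotin-labelled cDNA was hybridised to Affymetrix GeneChip Human Gene 2.0 ST arrays, which carry 1 sample in 1 colour.

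The authors deposited linear intensity values, 1 per array and transcript cluster (a set of probes along 1 gene), and per the series text analysed them in GeneSpring (Agilent). The background correction, normalization, summarization, any row filter and the authors' test were not given in the sources used here. That the values are linear intensities was judged from their range: the lowest was 18.9 to 19.0 and the highest 11521 to 13166 on the 8 arrays. Nearly equal quartiles point to a common scaling before deposit: the first quartile was 29.5 to 30.9, the median 49.3 to 53.5 and the third quartile 107.6 to 109.3. Such scaling would hide a change of all genes in one direction. The design table had been written for log2 values, so log2 of the deposited intensities was taken and the planned tests were kept. Raw probe signals and detection calls were not used here, so no statement is made on whether a gene was above background. Precision is limited by the number of arrays.

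The table held 44629 rows without missing values. The platform annotation gave exactly 1 gene symbol for 15835 rows, several symbols for 0 and none for 28794, which are unnamed here and were left out of the main tests. Symbols were compared, through gene identifiers, with a RefSeq table of the assembly GRCh38, and 0 changed. The named rows covered 14812 genes, of which 651 had more than 1 row and were represented by the brightest row. They include 11911 of the 20056 protein-coding genes in the reference table (59.4%), so many well-known genes were not analysed here. Genes whose mean log2 value lay under the 25th percentile (5.54, an intensity of 46.7) were left out, which removed 3703 genes and left 11109. Of these, 480 carry microRNA, other small RNA or LOC symbols; they were tested and counted but not named.

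The knockdown was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on log2 values) with cell line as a fixed block, and genes passed at a Benjamini-Hochberg adjusted p under 0.05. Lines are the replicates of the knockdown (n = 4). No line has replicate arrays, so differences within a line have no test. The pairing follows the cell line in the labels. As a check, each control array's deviation from the control mean correlated across genes at 0.925 to 0.932 with that of the knockdown array of its own line, and at -0.135 at most with that of any other line. Deviations from a group mean cancel out over the lines, which makes the values for other lines negative on average. The check thus rests on the high values within a line. For NSD2 and GLO1, an exact two-sided permutation test exchanged the labels within lines. Its smallest possible p is 0.125, so it could not pass 0.05. Differences between lines were tested with limma's moderated F test in the same fit.

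Before the data were examined, 26 gene lists, the tests, the rule for named genes and most alternatives were fixed. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. The named genes were up to 12 per direction past the threshold with the same sign in 4 lines, to be filled up with genes of at least 1.5-fold by unadjusted p (there were none), together with NSD2, GLO1, FGFR3 and the myeloma translocation genes. They also included up to 2 members per list and direction, 4 genes per direction within each line whose brighter array exceeded the median of the tested genes, and 4 genes per line that stood highest above the other lines.

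The alternatives were quantile normalization, centring on array medians, other filters on dim genes, the mean of a gene's rows, leaving out each line, no block, a random block, eBayes with trend and robust, array weights, an ordinary paired test, other thresholds and, added after the data were seen, all rows of the table and the tested genes without small RNA symbols. The fits were tested on simulated data with 200 of 11109 genes changed in 20 draws of the knockdown comparison. A log2 change of 0.4 was called in 86.7% of cases and one of 0.75 in 99.9%, and 5.12% of the calls were false. In the same way, a list shifted by -0.13 was called in 20 of 20 draws, and 0 of 460 tests of unshifted lists passed camera at the preset correlation. Simulated genes were independent of each other, which real genes of a pathway are not. The cutoff of the adjusted p also loosens as more genes change. With 13 calls in the real data it was stricter than with 200 changed genes, so the share of 86.7% is too high for the real data. No gene coordinates are given, because the deposited values name no genome build.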

Results

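Expression was measured on 8 arrays, 1 control and 1 MMSET I knockdown array from each of the t(4;14) myeloma lines KMS11, KMS18, KMS34 and OPM2. In this translocation the immunoglobulin heavy chain locus is joined to the region of NSD2, which encodes a histone H3 lysine 36 methyltransferase, and of the receptor gene FGFR3. The series title names GLO1 as a gene that MMSET I regulates. Arrays of the same line correlated across 11109 genes at 0.991 to 0.993 on the log2 scale, and arrays of different lines at 0.880 to 0.915. The first comparison asked what the knockdown changed across the 4 lines.

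The targeted gene was examined first. NSD2 had a mean intensity of 743 ± 55 (SD, n = 4) in control arrays and 656 ± 76 in knockdown arrays, a log2 difference of -0.18 with a standard error of 0.064. It was lower in 4 of 4 lines, by -0.13 in KMS11, -0.31 in KMS18, -0.14 in KMS34 and -0.16 in OPM2. The unadjusted limma p of NSD2 was 0.0132, but it did not pass limma's test over all genes (adjusted p = 0.472). The exact permutation test gave p = 0.125, the smallest it can give. The row for NSD2 covers the whole gene and does not separate the short isoform from the longer ones, so it is a weak check of the knockdown.

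GLO1, which encodes glyoxalase I, the enzyme that begins the glutathione-dependent detoxification of methylglyoxal, fell by 40.8% with the knockdown. Its mean intensity was 946 ± 129 (SD, n = 4) in control arrays and 566 ± 125 in knockdown arrays, a log2 difference of -0.76 with a standard error of 0.069 (limma, adjusted p = 0.00142). The difference was -0.65 in KMS11, -0.78 in KMS18, -0.66 in KMS34 and -0.94 in OPM2. The exact permutation test gave p = 0.125, the smallest it can give. GLO1 was the 1 gene of 11109 that was at least 1.5-fold lower or higher in the same direction in 4 lines. It missed the threshold without the cell line block (adjusted p = 1), in an ordinary paired test (0.484) and, in an alternative chosen after the data were seen, over all rows of the table (0.200).

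**Figure D1:**
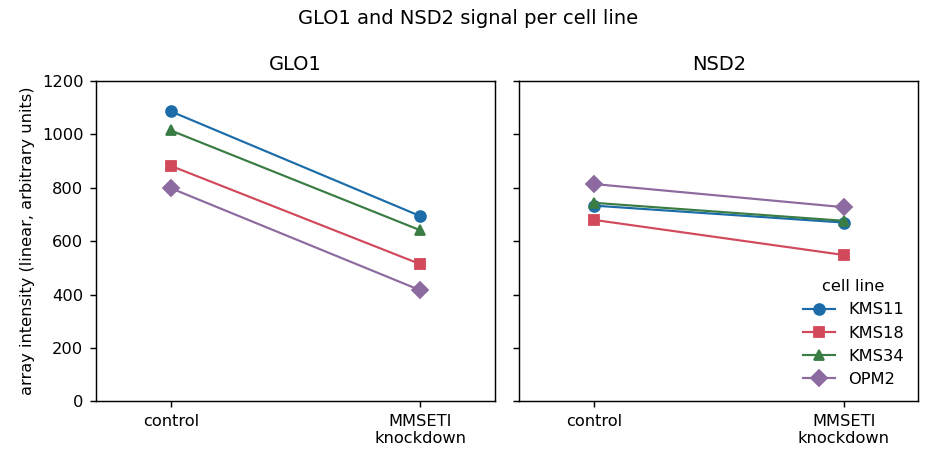
Intensities of GLO1 and NSD2 on the 8 arrays, control and knockdown, with a line joining the arrays of each cell line. GLO1 was lower with the knockdown by 0.65 to 0.94 log2 units in the 4 lines, and NSD2 by 0.13 to 0.31.

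With GLO1, 13 of the 11109 genes passed the threshold, 11 lower and 2 higher, and each had the same sign in 4 lines. One of the 11 carries a microRNA symbol and is only counted. The others that fell were POLR3G, a subunit of RNA polymerase III (log2 difference -0.53, adjusted p = 0.0147), CS, the citrate synthase of the citric acid cycle (-0.48, 0.0147), and SELENOF, a selenoprotein of the endoplasmic reticulum (-0.49, 0.0291). The kinase gene MAP3K3 had a difference of -0.46, the F-box protein gene FBXO21 of -0.44, the nucleolar protein gene RRP1B of -0.44 and the importin alpha gene KPNA6 of -0.42. The transcription factor gene KLF9 had a difference of -0.40 and BLOC1S6, which encodes a subunit of a complex for lysosome-related organelles, of -0.38. The 2 genes that rose were ANKRD52, a regulatory subunit of protein phosphatase 6 (log2 difference 0.46, adjusted p = 0.0422), and UGT8, the galactosyltransferase that makes galactosylceramide (0.42, 0.0422). The weakest call was MAP3K3 (adjusted p = 0.0473).

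Leaving out a line ended most of these calls. There were 4 calls without KMS11, 1 without KMS18, 2 without KMS34 and 1 without OPM2, and GLO1 was called each time. The called genes with a name kept their sign in each of these settings, with CS between -0.49 and -0.47, FBXO21 between -0.45 and -0.43, BLOC1S6 between -0.39 and -0.36 and ANKRD52 between 0.40 and 0.52. Centring each array on its median gave 0 higher and 7 lower calls, and limma without the cell line block gave 0, with 18 genes at an unadjusted p under 0.05. In the main test, 934 genes had an unadjusted p under 0.05, against 555 expected by chance, with 473 higher and 461 lower. Of the tested genes, 17.05% had the same sign in 4 lines, against 12.5% by chance.

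**Figure D2:**
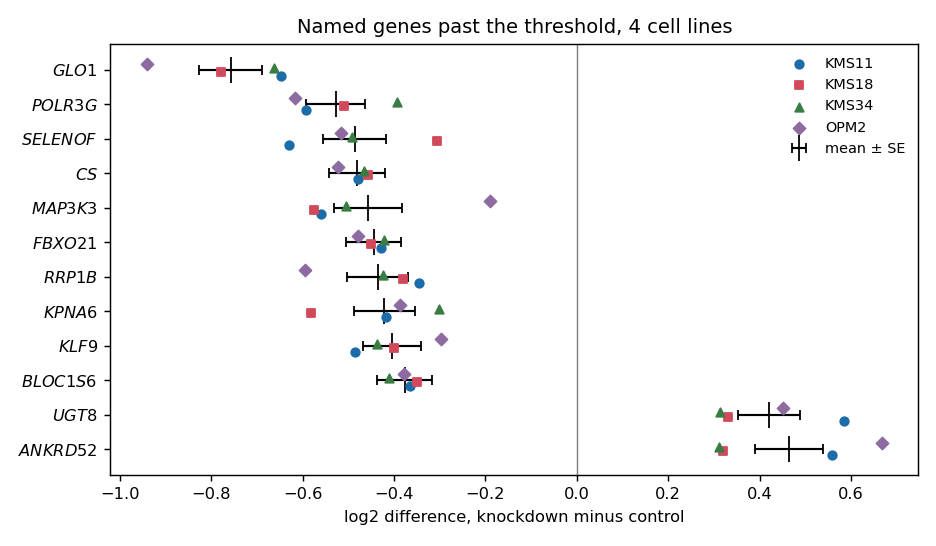
Log2 difference between knockdown and control (x axis) for the 12 named genes past the threshold (y axis), with 1 symbol per cell line and bars for the mean ± SE from limma. GLO1 lies lowest, at a mean of -0.76, and ANKRD52 highest, at 0.46.

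Most genes of the G1/S transition and DNA replication had a mean below 0, but whether the list passed depended on the test. Of 22 measured members, 21 had a mean below 0 and 1 above, with a median log2 difference of -0.13. Camera at the preset correlation of 0.01, which takes members as nearly independent, called the list (adjusted p = 1.19e-08). At the list's estimated correlation of 0.396 camera did not call it (adjusted p = 0.664), and neither did fry (adjusted p = 0.247). The small p at the preset correlation thus does not measure the spread over the lines. Camera with an estimated correlation rests on the spread over only 4 lines and had little power over 24 lists. Its miss therefore cannot decide against the list. The replicative helicase subunit gene MCM6 had a difference of -0.40 and missed the threshold over all genes (adjusted p = 0.0510), while it passed adjusted over the list alone (0.00141). The transcription factor gene E2F1 had a difference of -0.21 and the methylation maintenance factor gene UHRF1 one of -0.22, and neither passed over all genes or adjusted over the list alone. GINS1, at 0.06, was the member with a mean above 0.

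Mitotic genes of the G2/M list were lower in 18 of 25 members, with a median of -0.081 (camera, adjusted p = 0.0299, and 0.664 with an estimated correlation). CDC20 and BUB1, which act in the spindle checkpoint, each had a difference of -0.16, and the survivin gene BIRC5 one of 0.10. The list did not pass without KMS11 (adjusted p = 0.490) or without OPM2 (0.0528). MYC targets and ribosome biogenesis genes were lower in 14 of 17 members, with a median of -0.073 (camera, adjusted p = 0.0299, and 0.664 with an estimated correlation), and did not pass without OPM2 (0.486). Its members LYAR and DDX21, both nucleolar protein genes, had differences of -0.13 each.

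Glutathione and oxidative stress defence genes were lower in 13 of 15 members, with a median of -0.072 (camera, adjusted p = 0.0114, and 0.664 with an estimated correlation). The glutathione synthetase gene GSS and the heme oxygenase gene HMOX1 each had a difference of -0.19, and the peroxiredoxin gene PRDX4 one of 0.04. Without OPM2 this list did not pass (0.0815). In these 4 lists 0 members passed limma's threshold over all genes, and 1 (MCM6) passed adjusted over the list alone. At an unadjusted p under 0.05 were 9 members of the G1/S list, 4 of the G2/M list, 4 of the glutathione list and 0 of the MYC list, each of them lower. With camera at the estimated correlation 0 of 24 lists passed and 1, the glutathione list, had an unadjusted p under 0.05 (0.0387). Its unadjusted p was 0.110 for the G1/S list, 0.330 for the MYC list and 0.357 for the G2/M list. The shared value of 0.664 arises from the adjustment over lists. The estimated correlation was -0.024 for the glutathione list, 0.396 for G1/S, 0.363 for MYC and 0.316 for G2/M. For the glutathione list this lies below the preset of 0.01, yet its unadjusted camera p rose from 0.00095 to 0.0387. Correlation between members thus cannot alone account for the lost calls. With only 4 lines this form of camera had little power, so 0 of 24 does not decide against the lists. With fry 0 passed and 4 had an unadjusted p under 0.05, and the fry test for change in either direction passed 4 lists, those of glutathione defence, glyoxalases, H3K36 methylation and the small RNA pathway.

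The other 20 tested lists did not pass camera (smallest adjusted p = 0.0610). That value belongs to the H3K36 and H3K27 methylation machinery, of which 16 of 26 members had a mean below 0, with KDM4B and MTF2 at -0.22 each and NSD1 at 0.16. In the glyoxalase and methylglyoxal list (adjusted p = 0.410, 8 of 15 genes measured), GLO1 and the D-lactate dehydrogenase gene LDHD passed adjusted over the list alone. LDHD, at 0.30 and higher in 4 of 4 lines, did not pass over all genes (adjusted p = 0.203). The next enzyme of the pathway, HAGH, had a difference of 0.04 and the deglycase gene PARK7 one of -0.08. In the NF-kB list (0.575) the chemokine gene CCL3 had a difference of 0.42, which passed adjusted over the list alone (0.00284) and not over all genes (0.109).

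The remaining lists had adjusted camera p-values of 0.410 for glycolysis, 0.996 for oxidative phosphorylation, 0.918 for the BCL2 family and apoptosis, 0.932 for p53 targets and 0.422 for the unfolded protein response. They were 0.826 for plasma cell identity, 0.229 for cytosolic ribosomal proteins, 0.932 for genes around NSD2 on its chromosome arm, 0.229 for myeloma translocation targets and 0.932 for cell adhesion. They were 0.629 for the interferon response, 0.410 for the small RNA pathway, 0.229 for cholesterol biosynthesis and 0.816 for heat shock and immediate early genes. Lists of other cell types (T and NK cells, myeloid, stromal and endothelial) gave 0.410 to 0.930, and 0 of their 23 measured members passed limma's threshold, with 1 at an unadjusted p under 0.05 (CST3, 0.15). In the myeloid list 6 of 7 members had a mean below 0. Its median of -0.086 (-0.258 in KMS11) lay further below 0 than those of the glutathione, G2/M and MYC lists. Above 0 were 5 of 5 stromal and endothelial members (median 0.035) and 7 of 11 T and NK members (median 0.014). Median and test differed in direction for oxidative phosphorylation (median 0.0044, tested lower), NF-kB (median -0.0036, tested higher) and cell adhesion (median -0.012, tested higher). The proteasome and replication-dependent histone lists had 0 members with a named row and were not analysed here.

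**Figure D3:**
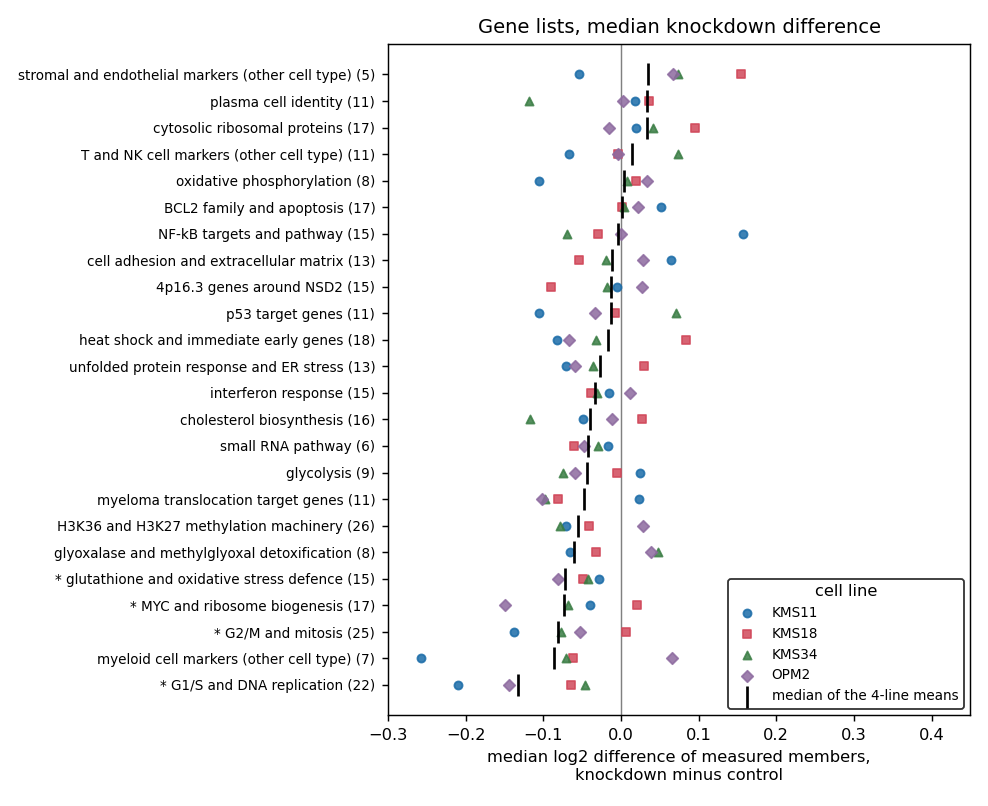
Median log2 difference between knockdown and control of the measured members of each tested gene list (x axis), over the 4 lines (bars) and in each line (symbols), with the number of measured members in parentheses and an asterisk at lists past camera's threshold at the preset correlation. The G1/S and DNA replication list lies lowest, with a median of -0.13 over lines, and the glutathione, G2/M and MYC lists lie between -0.072 and -0.081. The myeloid marker list, with 7 measured members and not past the threshold, lies below these last lists, at -0.086.

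Genes that myeloma translocations dysregulate were compared for the knockdown and between lines, and 0 passed limma's threshold for the knockdown, with NSD2, CCND2 and CCR1 at an unadjusted p under 0.05. FGFR3 had a log2 difference of -0.13 (adjusted p = 0.610), the cyclin gene CCND2 one of -0.15 (0.578) and the chemokine receptor gene CCR1 one of 0.22 (0.511). MYC had a difference of -0.04, MAF of -0.05, CCND1 of -0.08, CCND3 of 0.05, DSG2 of 0.00, CX3CR1 of -0.01 and MYEOV of -0.14. Control arrays of different lines covered wider ranges for several of these genes. MAF had an intensity of 1158 in KMS11, 414 in KMS34, 166 in OPM2 and 72.2 in KMS18. CCR1 had 481 in OPM2, 446 in KMS11, 276 in KMS34 and 56.3 in KMS18. FGFR3 ranged from 1061 in KMS34 to 2410 in KMS11, and NSD2 from 680 in KMS18 to 814 in OPM2. The F test between lines passed for these genes except CCND1 (adjusted p = 0.742).

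Within each line there was 1 array per condition, so the following values have no test. In KMS11, 30 genes were at least 1.5-fold higher and 27 at least 1.5-fold lower with the knockdown. Lower were the stress gene SESN2 (1.94-fold) and the serine synthesis genes PSAT1 (1.82-fold) and PHGDH (1.79-fold), as well as GGTLC2 (1.77-fold), whose signal is uncertain because of near-identical paralogs. Higher were S100A4 (2.07-fold), the thrombin receptor gene F2R (1.78-fold), GBP3 (1.62-fold) and GPR137B (1.61-fold). In KMS18, 5 genes were higher and 9 lower by that size. The fatty acid desaturase gene FADS1 was 1.98-fold lower, GLO1 1.72-fold, F2R 1.498-fold and KPNA6 1.496-fold lower. CDPF1 was 1.76-fold, RPL39 1.61-fold, SERF2 1.58-fold and TARS3 1.56-fold higher, of which RPL39 and SERF2 are uncertain because of pseudogenes and paralogs.

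In KMS34, 13 genes were at least 1.5-fold higher and 15 lower. The metallothionein gene MT2A was 1.71-fold, SIGLEC7 1.64-fold, PRB2 1.61-fold and GLO1 1.58-fold lower, and MT2A and PRB2 belong to families of similar genes. CHRDL1 was 1.69-fold, DES 1.58-fold, and YES1 and MOB1B 1.52-fold higher. In OPM2, 10 genes were higher and 11 lower. GLO1 was 1.92-fold, IGFBPL1 1.76-fold, DEPP1 1.57-fold and POLR3G 1.53-fold lower, while GLIPR1 was 1.69-fold, CTSO 1.68-fold, TRIB1 1.62-fold and ANKRD52 1.59-fold higher.

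The knockdown differences of the 4 lines were weakly correlated across genes. Over 6 pairs of lines, Pearson's r across 11109 genes ranged from 0.0329 for KMS18 and OPM2 to 0.116 for KMS11 and KMS18, with a mean of 0.0810, which was 0.126 with dim genes filtered at the 50th percentile. Spearman's rho ranged from 0.0185 to 0.117, with a mean of 0.0794. Genes are not independent replicates, so no p-value is given. Between 50.3% and 54.4% of genes had the same sign in a pair of lines.

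The second comparison asked how the lines differ from each other. Between lines, 8412 genes (75.7%) passed the moderated F test, and the line means of 2093 genes spanned at least 2-fold. The median range of line means was 0.516 log2 units, against a median absolute knockdown difference of 0.0571. The first is a range over 4 line means and the second 1 difference averaged over 4 lines. Noise alone would thus make the first larger. Where the next line's mean lay under the brightness limit of 46.7, the fold was taken against that limit and is given as "at least"; this floor was chosen after the data were seen. KMS11 stood above the next line in the endothelin receptor gene EDNRB (at least 14.9-fold), THEMIS (15.2-fold), LAPTM4B (14.1-fold) and NEB (11.8-fold). KMS18 stood above the others in the lymphocyte receptor gene BTLA, by at least 32.4-fold, with a control intensity of 1471, and in PLEK (10.6-fold), ESRP1 (8.36-fold) and C2CD4D-AS1 (6.80-fold). KMS34 stood highest in the annexin gene ANXA1 (17.02-fold), DCC (11.1-fold), BANK1 (at least 8.16-fold) and CD53 (at least 7.88-fold). OPM2 stood highest in the reelin gene RELN (11.1-fold), the metallothionein gene MT1G (at least 5.65-fold), IGFBPL1 (6.06-fold) and DSEL (4.60-fold). With the limit as a floor, 20 genes in KMS11, 11 in KMS18, 11 in KMS34 and 7 in OPM2 stood at least 4-fold above the other lines. The residual of this test is the spread of the lines' knockdown differences around their mean, so it rests on 1 culture pair per line.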

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

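The tests on the amino acid response genes were chosen after the result was seen. A line was singled out where its knockdown difference lay far from those of the other 3 lines. This was tested for 155 values (129 genes and 24 lists among them), and 9 were singled out. Chance alone would give 7.75 among values picked without regard to the outcome, but some of these genes, such as CDPF1, were named for a large difference in 1 line, so that number is not a fair yardstick here. The log2 differences were -0.25 for FGFR3 in KMS34 (-0.2548), 0.1722 for MYEOV, 0.14 for LDHD, 0.4543 for XIAP, -0.8164 for ASNS and -0.3162 for CD7 in KMS11, and 0.4095 for PGAM1 and 0.8139 for CDPF1 in KMS18. The ninth was the median of the myeloma translocation genes in KMS11, at 0.02382. F2R went in opposite directions, at 0.8318 in KMS11 and 0.6823 in OPM2 against -0.5833 in KMS18, a difference that was not tested.

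ASNS, the asparagine synthetase gene, led to a wider pattern in KMS11, where SESN2, PSAT1 and PHGDH also were lower with the knockdown. These are targets of the transcription factor ATF4. Of 29 measured genes of a list of 45 genes of the ATF4 and amino acid response, 27 were lower in KMS11, 6 of them by at least 1.5-fold, with a median of -0.435. Without the 4 genes that led to the list, 23 of 25 were lower, with a median of -0.277, below all 10000 random lists matched on brightness (95% of them between -0.0735 and 0.0727), which argues against a level-dependent bias between the 2 KMS11 arrays. With those genes, the median in KMS18 was 0.0775, above the central 95% of the random lists (up to 0.0648). Without those genes, the medians of the other lines were 0.062 in KMS18, -0.0095 in KMS34 and 0.028 in OPM2. Thus 0 other lines lay below the central 95% of the random lists. A difference in nutrients or growth state between 2 cultures may give such a pattern, and with 1 pair of arrays it cannot be told apart from an effect of the knockdown in KMS11.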

How the results depend on the processing

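Chosen after the data were seen were the tests over all rows of the table and those without small RNA symbols. Of the results that answer a comparison, 361 values under an alternative kept direction and side of the threshold, 20 lost the threshold, 2 gained it and 21 moved. Direction was judged only where a result passed on either side, and none reversed. Of the other values, for single genes, 1449 were the same, 86 weaker, 4 stronger (MCM6 in 3 settings, CCL3 in 1) and 4 moved. Most of these genes did not pass in the main test, so the 1449 say little about the calls. Of 14 settings, POLR3G and CS passed in 9, FBXO21 in 8, and SELENOF and RRP1B in 6. MAP3K3, KPNA6, KLF9, BLOC1S6, ANKRD52 and UGT8 passed in 5 each. The causes were not tested, except where fewer lines or a larger number of tested rows are part of the alternative itself.

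Against 13 calls, there were 7 after centring on array medians, 4 without the filter on dim genes, 3 with the line as a random block, 29 with trend and robust, 1 at 1.5-fold or more, 4 over all rows with trend and robust, and 1 to 4 without 1 line. Among these, 7, 4, 3, 13, 1, 3 and again each of the 1 to 4 were shared with the 13. Without the cell line block (the pairing) there were 0 calls, with an ordinary paired test 0 and over all rows 0, and these had 18, 823 and 3063 at an unadjusted p under 0.05. GLO1 passed in 14 of 17 settings, with differences from -0.79 to -0.70 and adjusted p from 6.38e-06 to 1. It missed in 3, each at a difference of -0.7575: no block (1), ordinary paired test (0.484) and all rows (0.200). NSD2 passed in 0 of 14 settings (adjusted p 0.205 to 1).

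Against 4 lists, there were 2 with quantile normalization, 1 without the block, 0 with an estimated correlation and 0 with fry, and 1 to 4 without 1 line. G1/S genes had 0.664 with an estimated correlation and 0.247 with fry. The G2/M list had 0.0747 with quantile normalization, 0.169 without the block, 0.664 with an estimated correlation and 0.511 with fry, and 0.00657 to 0.490 without 1 line. The MYC list had 0.0747, 0.110, 0.664 and 0.511 in the same settings, and 0.0141 to 0.486 without 1 line. The glutathione list had 0.0792 without the block, 0.664 with an estimated correlation, 0.242 with fry, and 0.00701 to 0.0815 without 1 line. The H3K36 list passed without the filter (0.0328) and with trend and robust (0.0280). The mean agreement between lines was 0.126 with the filter at the 50th percentile, and 0 genes were concordant at 2-fold and 13 at 1.2-fold. Over 13 alternatives the adjusted p ranged up to 0.664 for each of these 5 lists, from 2.20e-11 for G1/S, 0.00534 for G2/M, 0.00921 for MYC, 0.00249 for glutathione and 0.0280 for H3K36. The block changed no other list's call. Signal over background cannot be judged here, since raw probe signals were not used.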

Other observations

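The tests for an off-target effect on GLO1 and for a level-dependent bias in the G1/S genes, and the limit of the counted splits to those that part every line, were chosen after the results were seen. The rows without a gene name held no further calls. Of 28794 such rows, 12697 reached the brightness limit, and limma called 0 (smallest adjusted p = 0.150), with 836 at an unadjusted p under 0.05 against 635 expected by chance. Small RNA and LOC symbols made up 4.32% of the tested genes but 23.7% (27 of 114) of the genes at least 1.5-fold apart in any line. Their median SD over lines was 0.172, against 0.127 for other genes, and their median log2 level was 6.33, against 6.95.

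GLO1 fell by more than the NSD2 signal did, in 4 of 4 lines. Compression of the NSD2 signal at its brightness was examined through other genes of that brightness. Of the genes within 0.25 log2 units of its mean, 26.6% had line means that span at least 2-fold. Signals of that brightness can thus differ widely, but other genes cannot show how the NSD2 row itself responds, so compression there stays undecided. The NSD2 row may also hardly see the short isoform, whose own level was not measured here. The shRNA may also have acted on GLO1 or other genes directly. Of the called genes, 11 were lower, as a wider effect of NSD2 would also give, and without the shRNA sequence these cannot be told apart.

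The lower G1/S and DNA replication genes form the other pattern across lines. Their median of -0.133 over lines lay below all 10000 random lists matched on brightness (95% between -0.0499 and 0.0356), which argues against a level-dependent bias, and without MCM6 the list still had an adjusted p of 2.91e-07 in camera at the preset correlation, which argues against a single gene. The call itself is lost for the full list with an estimated correlation (adjusted p = 0.664), in a test with little power on so few lines. By line the medians were -0.21 in KMS11, -0.14 in OPM2, -0.064 in KMS18 and -0.046 in KMS34, where 23.2% of random lists lay lower. Growth differences between cultures may also give this. Of the 8 exchanges of control and knockdown within lines, 1 (the real one) gave as small a p, with the next at 4.3e-08, and 8 are too few for a share under 0.05. The contrast of knockdown with control in KMS11 and OPM2 alone gave a smaller p (5.55e-12) than the real one (4.96e-10). It keeps the real labels in the 2 lines with the lowest medians, so it is no yardstick for chance.

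Other splits of the 8 arrays into 4 and 4 were fitted with the line as a block. Because arrays are paired by line, only the 8 splits that part every line can be set beside the real one, so the planned share over 35 splits was not used. Of the 8, 1 (the real split) called as many as 13 genes, with 0 as the highest other, and 1 called as many as 4 lists, with 3 as the highest other. The split with 3 lists exchanges the labels of KMS18 alone, so it keeps the real labels in the other lines. These 8 splits are too few for a share under 0.05. Of the remaining splits, 3 could not be fitted, and 24 part only 2 lines. These 24 rest on the lines they part and come in pairs with the same fit. They called at most 0 genes and 4 lists. The pair with 4 lists sets knockdown against control in KMS34 and OPM2, so it is no yardstick for chance.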
